A study of Mus musculus with 11 samples.

How the data were processed

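RNA was sequenced from CD8 T cells sorted out of mouse B16 melanomas, in 2 sets of libraries. The Poly set held polyclonal T cells from tumours of vaccinated wild-type (WT) mice, with 3 libraries, and of mice lacking LRIG1 (LRIG1 KO), with 2 libraries. All Poly libraries are titled female, and the OT1 titles give no sex. The OT1 set held WT and LRIG1 KO OT-I cells, which carry a transgenic receptor for an ovalbumin peptide. Both kinds were transferred together into the same mice bearing B16 tumours that express ovalbumin, and gave 3 libraries per genotype. Per the labels, each library is an independent replicate, pooled from 4 to 5 tumours in the Poly set and from 2 to 3 in the OT1 set. The sampling day is given as 18 in the sample labels and 19 in the series text for Poly, and as 8 and 7 for OT1. Per the labels' protocols, Poly libraries were made from 100 ng of RNA with a SMART-Seq v4 kit and OT1 libraries from 200 ng with a TruSeq mRNA kit, so kit, tumour, day and T cell population all differ between the sets.

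The authors deposited a table of read counts per gene for each set, with whole numbers that were not normalized. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner and the counting program, and whether counting used strand, are not given in the sources used here. Totals ran from 24.7 to 33.7 M counts per library in the Poly set and from 21.2 to 24.3 M in the OT1 set. A count of 0 in a library allows up to 0.122 CPM (counts scaled to the same library total) in the Poly set and 0.142 in the OT1 set, as the limit of 3 counts in the shallowest library, for counting error only. The counts covered 23917 genes in the Poly set and 25193 in the OT1 set. Missing symbols were filled in from a reference table for 6341 of 6384 genes in the Poly set and 6711 of 6755 in the OT1 set, and the others kept their identifiers. Gene positions came from the gencode annotation of the same build. Replicates of a group differed by 5.75 to 30.2 times sampling noise (chi-square over degrees of freedom, genes with at least 50 counts), so no library was counted as a copy of another.

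Each set was tested within its own table with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, and the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 15842 genes in the Poly set and 14909 in the OT1 set. The difference between the sets was tested as an interaction in 1 fit of all 11 libraries with a term for the 4 groups, over 16998 genes. Standard errors of log2 fold changes were derived from the F statistic. The means given are TMM-scaled CPM. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 3 tested members. Camera with an estimated correlation, and fry, were run beside it. The 29 lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Lrig1 and, per comparison, up to 8 genes with the largest change in each direction among those past the threshold, with a mean log2 CPM of at least 2 and every KO library beyond every WT library. It left out predicted genes, clone names (read here to include names of the form of letters, digits and a version), pseudogenes, ribosomal protein genes and receptor segments. It added up to 4 called members of each list, fixed markers of T cell state and function whatever their p (of 8, 1 is not reported here), and up to 5 interaction genes per direction. A few further list members are given as examples, with the side of the threshold they fell on.

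Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means. In the OT1 set, same-numbered libraries gave 0.29, 0.17 and 0.17, so the numbers were read as pairs and a fit with the replicate number as a block is given beside results it changes. Libraries of unequal number ran from -0.29 to 0.13. Deviations from a group mean sum to 0, so these correlations are not independent, and with 3 libraries per group they are weak ground for pairs. This reading of the numbers rests on the data, since the labels do not say what a number marks. The main fit stayed without the block, as fixed beforehand. Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, no filter, a filter at 5 CPM, robust estimation off, a fold minimum, a threshold of 0.1, 1 fit of all libraries, the replicate block, and leaving out each library in turn. After the data were seen, a fit was added that removes each library's loess trend on transcript GC content, alone and with the block, and camera was run on the interaction. In simulated counts with 200 changed genes, the OT1 test on 14638 genes found 40.9% of changes of 0.5 in absolute log2, 74.6% of 1 and 93.9% of 2, with 7.95% false calls. The Poly test on 15296 genes found 18.2%, 55.2% and 79.1%, with 8.93% false calls. The interaction test on 16400 genes found 4.55%, 59.7% and 88.1%, with 4.67% false calls. False calls in the simulations of the separate sets therefore lay above the nominal level. The shares found rest on 1 simulated draw per comparison. Changes were placed only on genes with a mean of at least 1 CPM, so the shares do not cover lower genes. The interaction draw gave both sets the same mean per gene and changed only OT1 KO, unlike the real sets. With the GC trend removed, the OT1 test found the same shares of the simulated changes, with 9.15% false calls, in simulated libraries that held no such trend.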

Results

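The libraries measured transcript levels in tumour-infiltrating CD8 T cells with and without LRIG1, a transmembrane protein of the leucine-rich repeat family. The Poly set compared 2 LRIG1 KO with 3 WT libraries and the OT1 set compared 3 with 3. Depth was 24.7 to 33.7 M counts per library in the Poly set and 21.2 to 24.3 M in the OT1 set.

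Lrig1 transcripts remained detectable in every KO library. Lrig1 (ENSMUSG00000030029, GRCm38 chromosome 6, 94604529 to 94700158) measured 5.14 CPM ± 0.808 (SD, n = 2) in Poly KO and 11.8 CPM ± 3.62 (SD, n = 3) in Poly WT. The KO libraries held 150 and 142 counts, and the WT libraries 321, 403 and 279. In the OT1 set, Lrig1 measured 3.87 CPM ± 0.410 (SD, n = 3) in KO and 5.40 CPM ± 1.12 (SD, n = 3) in WT, with 75, 89 and 101 counts in KO and 150, 105 and 112 in WT. The log2 fold changes were -1.20 (SE 0.287) and -0.48 (SE 0.206). Neither passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.475 and 0.832), while DESeq2 called the Poly difference (adjusted p = 0.0204). All KO libraries lay below all WT libraries within each set, which chance gives in 10% of genes in the Poly set and 5% in the OT1 set. The part of the gene that was deleted is not given in the labels, so these gene totals do not show whether the deleted part was transcribed.

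**Figure D1:**
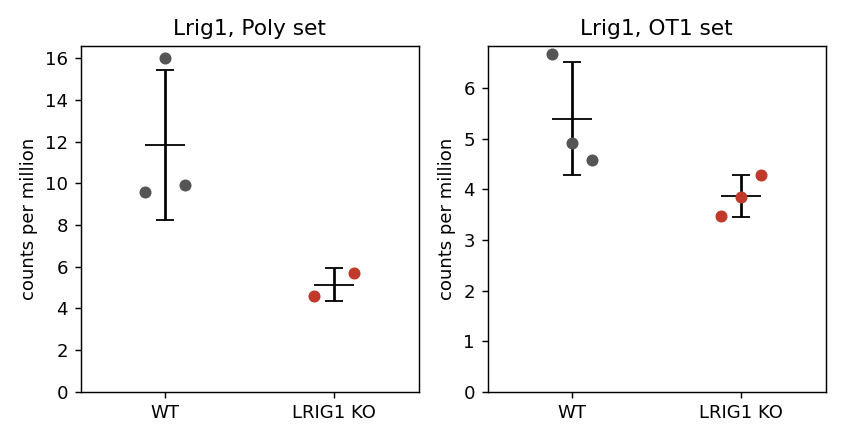
Lrig1 in CPM per library (points), with group mean and SD (bars), in the Poly set (left) and the OT1 set (right). KO means were 5.14 and 3.87 CPM and WT means were 11.8 and 5.40 CPM.

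In polyclonal T cells, few transcripts were called as different between LRIG1 KO and WT. Erdr1, annotated on both sex chromosomes, fell from 79.4 CPM ± 9.38 (SD, n = 3) in WT to 0.687 CPM ± 0.110 (SD, n = 2) in KO at the copy annotated on chromosome Y. The Poly libraries are titled female, so reads counted at that copy do not show a Y chromosome. Ifi208, of the interferon-inducible p200 family, fell from 51.6 CPM ± 6.25 to 14.1 CPM ± 1.83, and Dnaaf5, a dynein assembly factor, fell from 24.7 CPM ± 1.78 to 9.93 CPM ± 0.569. The receptor segment Trav14d-3-dv8 fell from 6.72 CPM ± 2.36 to 0.358 CPM ± 0.119.

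In all, 13 of 15842 genes changed, 4 higher and 9 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The adjusted p was 4.99e-06 for Erdr1 at the chromosome Y copy, 0.00500 for Ifi208, 0.0354 for Dnaaf5 and 0.0163 for Trav14d-3-dv8. DESeq2 called 96 genes. Of the 15842 tested genes 1094 had an unadjusted p under 0.05, where chance alone gives a share of 0.05. Of the 13, 9 were predicted genes, clones, ribosomal protein genes or receptor segments. The chromosome X and Y copies of Erdr1 are near-identical and share reads, so they are uncertain as separate genes. The call of Dnaaf5 was lost in each of the 5 fits that left out a library, up to an adjusted p of 0.316, the call of Ifi208 was lost without KO replicate 3 (adjusted p = 0.0914), and that of Trav14d-3-dv8 was lost in 2 of the 5, up to 0.231. With limma-voom Dnaaf5 and Trav14d-3-dv8 were not called (adjusted p = 0.0614 and 0.202). The count of calls fell to 8 without WT replicate 3 or KO replicate 1 and to 5 without KO replicate 3, and rose to 21 without WT replicate 2.

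By camera with a preset correlation, genes of cell division lay higher and genes of stem-like and memory T cells lay lower in Poly KO as lists, and no member of either passed over all genes. Both calls were lost with an estimated correlation (adjusted p = 0.987 with an estimated correlation) and with fry (adjusted p = 0.592). Of 43 cell cycle genes, 41 had a log2 fold change above 0, with a median of 0.25, and no member rose or fell over all genes or adjusted over the list alone. Every KO library lay above every WT library for 27 of the 43, and below for 0. Mki67, a marker of proliferating cells, measured 333 CPM ± 38.6 (SD, n = 2) in KO and 225 CPM ± 32.7 (SD, n = 3) in WT. Of 22 stem-like and memory genes, 19 lay below 0, with a median of -0.56. Adjusted over the list alone, 2 passed. Every KO library lay below every WT library for 10 of the 22, and above for 0, where chance gives 10% of genes each way. Genes that move together make such counts not independent. Without WT replicate 2 the mean of the list moved from -0.47 to -0.31, and Tcf7 from -0.70 to -0.43. That library stood at 50.3 on the first principal component of the Poly set, the other WT libraries at 2.53 and 8.10, and the KO libraries at -12.4 and -48.5. Klf3, a transcription factor, measured 15.8 CPM ± 0.0727 in KO and 34.9 CPM ± 5.75 in WT, and Tcf7, which encodes the factor TCF-1, measured 118 CPM ± 23.5 and 193 CPM ± 58.6. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.475 for Mki67, 0.105 for Klf3 and 0.602 for Tcf7. DESeq2 called Mki67 (adjusted p = 0.0195), and so did the fit of all 11 libraries with edgeR (0.0384).

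Camera with a preset correlation called 6 of 26 lists in the Poly set, with adjusted p = 5.66e-11 for cell cycle and 1.28e-05 for stem-like and memory genes. It also called trafficking and adhesion receptors (median -0.23, adjusted p = 0.0117), natural killer cell markers (median -0.66, adjusted p = 0.0142), tissue residency (median -0.28, adjusted p = 0.0425) and V segments of the OT-I receptor (median -0.82, adjusted p = 0.0425), all lower. With an estimated correlation none of the 6 was called (adjusted p = 0.987 with an estimated correlation for each), and fry called 0. Adjusted over the list alone, 2 trafficking genes, 1 natural killer gene and 1 V segment passed lower, and 0 tissue residency genes did. Over all genes, only the V segment passed. The natural killer call was lost without WT replicate 1 or KO replicate 3 (adjusted p = 0.0741 and 0.119). The trafficking call was lost without WT replicate 2 or KO replicate 3 (0.203 and 0.263), where the mean of the list moved from -0.24 to -0.10 and -0.15. Tissue residency was lost without WT replicate 2, WT replicate 3 or KO replicate 3 (0.166, 0.124 and 0.934), and its mean of -0.26 ran from -0.52 without KO replicate 1 to -0.0040 without KO replicate 3. The V segments were lost without WT replicate 2, KO replicate 1 or KO replicate 3 (0.262, 0.109 and 0.149), and their mean moved from -0.81 to -0.53 without WT replicate 2. Summed natural killer markers ran from 64.8 to 83.3 CPM in KO libraries and from 105 to 136 CPM in WT libraries.

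No cytotoxic effector or exhaustion gene passed over all genes in the Poly set. Of 32 cytotoxic effector genes and 27 genes of inhibitory receptors and exhaustion, 0 passed over all genes (edgeR). Adjusted over the list alone, 1 effector gene passed higher and 2 lower, and 0 exhaustion genes did. Every KO library lay above every WT library for 2 effector and 7 exhaustion genes, Pdcd1 among them, and below for 7 and 4, where chance gives 10% of genes each way. Pdcd1, which encodes PD-1, measured 1381 CPM ± 50.6 (SD, n = 2) in KO and 1208 CPM ± 71.5 (SD, n = 3) in WT. Gzmb, encoding granzyme B, measured 1843 CPM ± 156 and 1487 CPM ± 503, and Ifng, encoding interferon gamma, measured 219 CPM ± 55.3 and 224 CPM ± 7.99. Macrophage markers had a median of 0.29 and were not called (adjusted p = 0.0730 by camera), and melanoma markers had a median of 0.09 (adjusted p = 0.892).

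In OT-I cells transferred into the same mice, LRIG1 KO libraries held more transcripts of several single genes and less of several macrophage, class II and receptor genes. Ctse, which encodes the protease cathepsin E, rose from 21.8 CPM ± 0.910 in WT to 296.5 CPM ± 11.3 in KO (SD, n = 3 each). Ifi208 rose from 11.4 CPM ± 1.45 to 66.5 CPM ± 3.38, Ptprv, a receptor phosphatase gene, from 19.4 CPM ± 5.67 to 98.3 CPM ± 7.09, and Xlr3b from 0.260 CPM ± 0.0960 to 8.51 CPM ± 0.890. Rab4a, encoding an endosomal GTPase, and Camk2b, a kinase gene, fell, to 3.05 CPM ± 0.562 and 3.58 CPM ± 0.290 in KO, with log2 fold changes of -2.19 and -1.85.

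By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 74 of 14909 genes changed in the OT1 set, 17 higher and 57 lower. The adjusted p was 6.01e-09 for Ctse, 2.57e-06 for Ifi208, 1.51e-04 for Ptprv, 1.32e-05 for Xlr3b, 1.58e-04 for Rab4a and 3.12e-04 for Camk2b, and each was called in all 6 fits that left out a library. DESeq2 called 118 genes. Of the 14909 tested genes 786 had an unadjusted p under 0.05, where chance alone gives a share of 0.05. With the replicate number as a block, 145 genes were called, 27 higher and 118 lower. Wdfy1, Mid1 and Erdr1 also rose, with log2 fold changes of 1.07, 1.77 and, for the near-identical copies of Erdr1 on chromosomes Y and X, 1.84 and 1.73. The count fell to 45 without KO replicate 1. Mid1 was not called in the fit of all 11 libraries (adjusted p = 0.245).

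**Figure D2:**
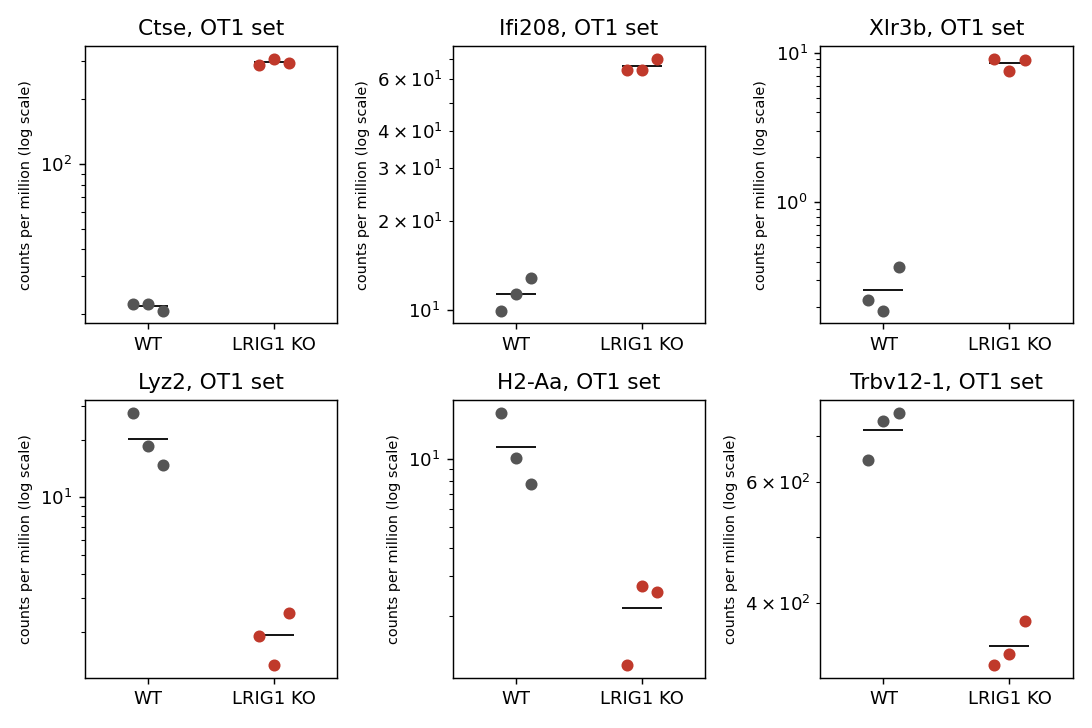
CPM per library on a log axis (points), with group means (bars), for 6 genes of the OT1 set. Mean levels in KO and WT were 296.5 and 21.8 CPM for Ctse, and 1.92 and 20.2 CPM for Lyz2.

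Of 18 tested macrophage and monocyte markers, 6 fell in OT1 KO, 0 rose and 12 did not pass, and 15 passed lower adjusted over the list alone. Lyz2, encoding lysozyme, fell from 20.2 CPM ± 6.63 to 1.92 CPM ± 0.583 (SD, n = 3 each), and Mpeg1, encoding perforin-2, fell from 9.18 CPM ± 1.05 to 1.68 CPM ± 0.239. Of the dendritic cell list, 4 of 8 fell, and all 4 encode the class II antigen presentation machinery: H2-Eb1, H2-Aa, H2-Ab1 and the invariant chain gene Cd74. Cd74 fell from 29.6 CPM ± 9.75 to 6.69 CPM ± 0.246. The same 4 passed adjusted over the list alone. The adjusted p by edgeR's quasi-likelihood test was 2.53e-04 for Lyz2, 1.86e-04 for Mpeg1 and 9.56e-04 for Cd74. In the fit of all 11 libraries, with a spread shared with the Poly set, Lyz2 and Mpeg1 were not called (adjusted p = 0.758 and 0.0866). H2-Ab1 was lost without KO replicate 1 or 3 and with limma-voom (adjusted p = 0.0962, 0.0905 and 0.0719), and H2-Aa when the GC trend was removed (adjusted p = 0.106, and 0.231 with the replicate block). Camera gave adjusted p = 3.15e-20 for the macrophage list (median -1.79) and 8.66e-06 for the dendritic list (median -1.02). These were adjusted p = 0.163 and 0.352 with an estimated correlation, and fry called the macrophage list (adjusted p = 0.0103) but not the dendritic list (0.0948). With the replicate block, fry did not call the macrophage list (adjusted p = 0.109). Melanoma markers had a median of 0.01 (adjusted p = 0.404 by camera).

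Transcripts of 2 V segments on the OT-I receptor list fell in OT1 KO. Trbv12-1 (GRCm38 chromosome 6, 41113550 to 41114067), the V segment of the beta chain, fell from 714 CPM ± 58.8 to 346.5 CPM ± 26.7 (SD, n = 3 each), a log2 fold change of -1.04 (SE 0.088). Trav14d-1, of the alpha chain family, fell from 206 CPM ± 24.0 to 91.4 CPM ± 10.2, a log2 fold change of -1.17 (SE 0.110). The adjusted p was 2.65e-04 and 5.95e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the fit of all 11 libraries, with a spread shared with the Poly set, neither was called (adjusted p = 0.99987 and 0.164). Of 5 tested V segments on the list, 2 fell and 3 did not pass, with the same count adjusted over the list alone. Reads of similar V segments can be shared, so the split between members is uncertain. Camera gave adjusted p = 0.00263 for the list, and adjusted p = 0.294 with an estimated correlation, while fry called it (adjusted p = 0.0103), but not with the replicate block (adjusted p = 0.190). The camera call was lost without KO replicate 2 (adjusted p = 0.108). Among 16 T cell identity genes only Trbc2, encoding a beta chain constant region, fell (log2 fold change -0.47, edgeR adjusted p = 0.0263), and it was lost in 4 of 6 fits that left out a library, up to an adjusted p of 0.181.

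By camera with a preset correlation, interferon-response and immediate early genes lay higher as lists in OT1 KO by small amounts (adjusted p = 0.00552 and 9.47e-04). Neither call was kept with an estimated correlation (adjusted p = 0.471 and 0.699 with an estimated correlation). Of 35 type I interferon genes 24 lay above 0, with a median of 0.05, and Ifi208 alone rose, also adjusted over the list alone. Ifi208, at a log2 fold change of 2.55, was the highest member, against a list mean of 0.14. The list was not tested without it. Of 30 immediate early genes 27 lay above 0, with a median of 0.14, and none rose or fell over all genes or adjusted over the list alone (edgeR). The immediate early call was lost when the GC trend was removed (adjusted p = 0.0609), but not with the replicate block as well (adjusted p = 0.0174), and in both the mean of the list moved from 0.16 to 0.07. It was also lost without KO replicate 2 (mean 0.03, adjusted p = 0.438), and the interferon call was lost without WT replicate 1 or KO replicate 3 (adjusted p = 0.226 and 0.0759). The median of GC-rich genes minus that of GC-poor genes was 0.37 in log2 in KO replicate 2 and -0.31 in WT replicate 3, relative to the mean of the 6 libraries. Markers of stroma and endothelium lay lower (median -1.13, camera adjusted p = 0.00368), with 0 of 7 members called by edgeR over all genes and 5 lower adjusted over the list alone. That list gave adjusted p = 0.471 with an estimated correlation. Summed over the list, levels overlapped, at 40.3 to 44.9 CPM in KO libraries and 42.2 to 51.1 CPM in WT libraries. The lower median therefore does not show a fall of the list's total level.

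No effector or exhaustion gene passed over all genes in the OT1 set. Of 31 cytotoxic effector genes, 27 inhibitory receptor and exhaustion genes, 22 stem-like and memory genes and 43 cell cycle genes, 0 passed over all genes or adjusted over the list alone (edgeR). Their medians were -0.08, 0.02, 0.06 and 0.03. Every KO library lay above every WT library for 2 effector genes and below for 6, Ifng among them, where chance gives 5% of genes each way, and 0 exhaustion genes were separated either way. Ifng measured 242 CPM ± 7.36 in KO and 301 CPM ± 27.9 in WT (SD, n = 3 each; edgeR adjusted p = 0.311, 0.0274 without WT replicate 1, and 0.00123 with the GC trend removed and the replicate block), Gzmb 4422 CPM ± 23.4 and 4471 CPM ± 246, and Pdcd1 733 CPM ± 56.1 and 649 CPM ± 71.8.

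**Figure D3:**
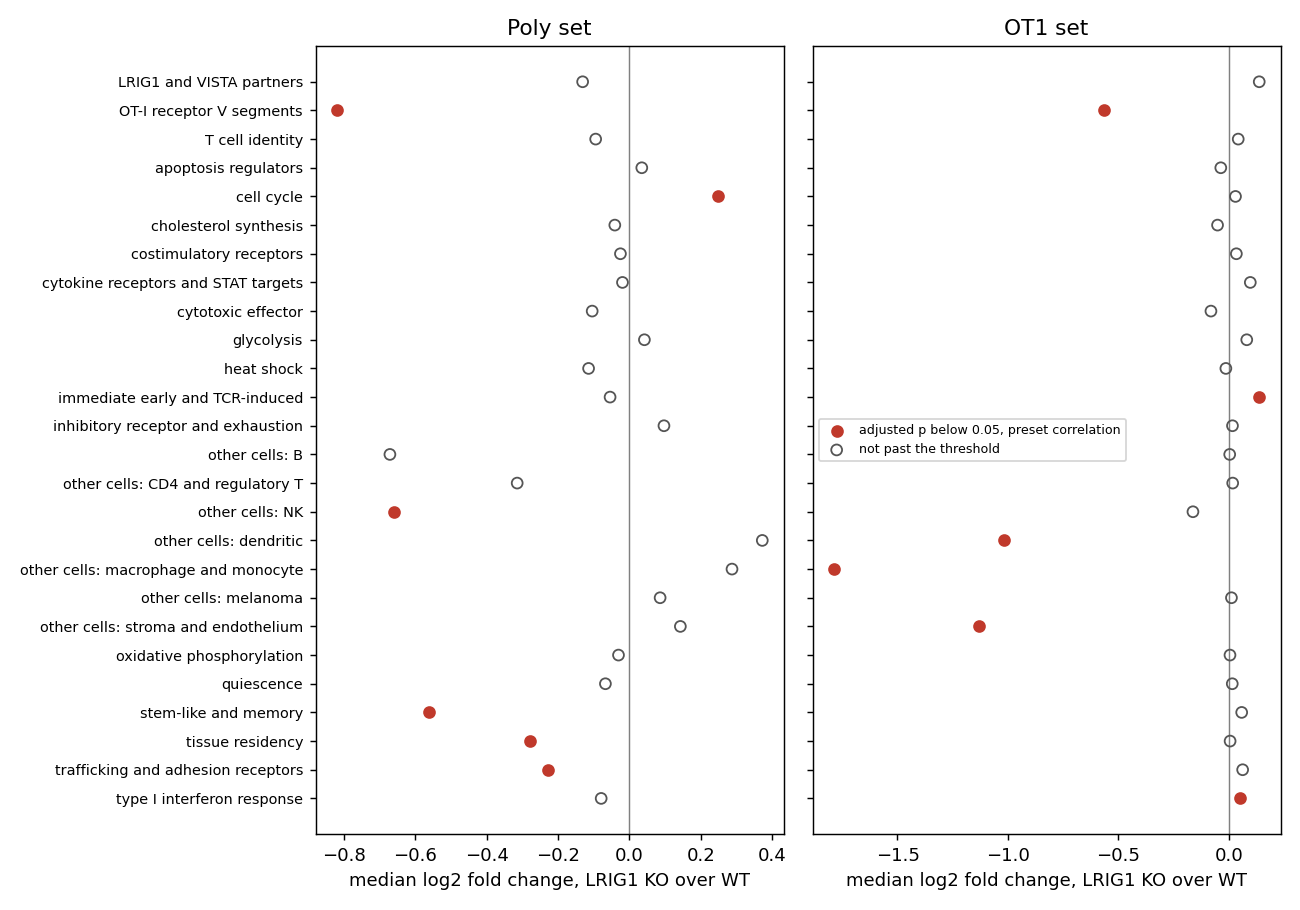
Median log2 fold change of LRIG1 KO over WT for each tested gene list in the Poly set (left) and the OT1 set (right). Filled points passed camera with a preset correlation (6 in each set) and none of them passed with an estimated correlation.

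The responses of the 2 populations were compared gene by gene. Across 13917 genes tested in both sets, log2 fold changes had a Pearson correlation of 0.0026 and a Spearman correlation of 0.084, and 54.2% had the same sign. These are correlations across genes, which are not independent replicates. Only 68 of these genes were called in either set, and noise in the fold changes of the others also brings a correlation toward 0. The low values therefore do not show that the responses were unrelated. Of 11 identifiers called in both sets, 2 were higher in both and 4 lower in both, where independent lists would share 0.0046 and 0.029. All 6 were predicted genes, a clone or the ribosomal protein gene Rps3a2. The other 5 went in opposite directions: the copies of Erdr1, Ifi208, Gm42047 and Gm47761.

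**Figure D4:**
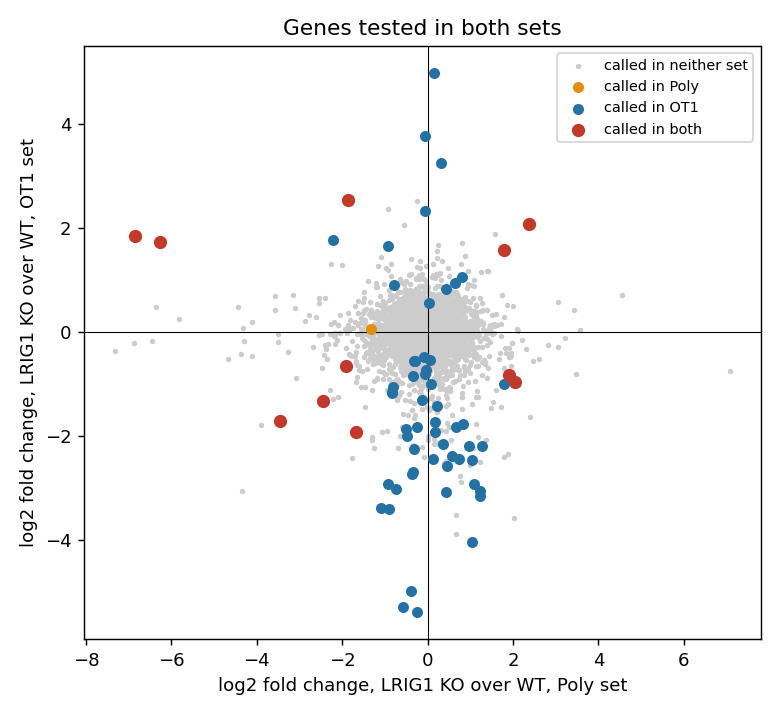
Log2 fold change of LRIG1 KO over WT in the Poly set (horizontal axis) and the OT1 set (vertical axis) for 13917 genes tested in both. Colours mark genes called in neither, either or both sets, and 5 of the 11 called in both lie in opposite directions.

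In the test of the difference itself, 37 of 16998 genes had a KO effect that differed between the sets, 18 with a higher and 19 with a lower log2 fold change in OT1 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). The count was 94 with the replicate block, 114 with DESeq2, and 1213 at an unadjusted p under 0.05, where chance alone gives a share of 0.05. Without Poly WT replicate 2 it rose to 59. Ctse differed by 3.81 (SE 0.179) and Rab4a by -3.17 (SE 0.299), with adjusted p = 7.33e-10 and 2.01e-05. Ctse in the Poly set measured 16.0 CPM ± 0.814 in KO and 16.6 CPM ± 3.34 in WT. The difference cannot be assigned to the T cell population, because library kit, tumour line and day also differ between the sets. Poly cells also came from vaccinated mice, with the genotypes in separate mice, while OT1 cells of both genotypes were transferred into the same mice. Differences in the background of the KO and WT mice, weighed below for Ctse among others, cannot be set apart here either.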

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

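All tests of explanations here were chosen after the result was seen, except the count over other splits of the libraries, and so was the list test of the difference between sets.

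Results stood out because the LRIG1 KO effect differed between the OT1 and Poly sets in the interaction test of edgeR. This held for 37 genes. The log2 difference, OT1 minus Poly, was 8.69 and 7.99 for the chromosome Y and X copies of Erdr1, 4.41 for Ifi208, 3.81 for Ctse, 4.84 for Xlr3b, 2.39 for Ptprv and 1.37 for Dnaaf5. It was -3.17 for Rab4a, -2.53 for Cd74, -3.50 for H2-Eb1, -2.97 for H2-Aa, -2.61 for H2-Ab1, -3.18 for C1qb and -4.75 for Lad1. Adjusted p ran from 1.52e-12 for Erdr1 to 0.04997 for Lad1. Among gene lists, camera with a preset correlation gave a median log2 difference of -2.32 for macrophage and monocyte, -0.94 for dendritic, -1.46 for neutrophil and -0.20 for cell cycle genes. It gave 0.56 for stem-like and memory, 0.20 for trafficking, 0.16 for type I interferon and 0.13 for immediate early genes. The neutrophil list had only 5 tested members here and was near the floor. It summed to between 0.0353 CPM in Poly WT replicate 3 and 5.74 CPM in OT1 WT replicate 3. No list was called with an estimated correlation (lowest adjusted p = 0.412).

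Trbv12-1 and Trav14d-1, of 5 tested V segments on the OT-I receptor list, fell in OT1 KO. Other T cells in the sorts are argued against, because at most 0.874% of TRBV reads in a KO library came from segments other than Trbv12. A general fall of receptor complex transcripts is argued against as well, because Cd3d, Cd3e, Cd3g and Cd247 had a median log2 fold change of -0.0016. Fewer copies of the receptor transgenes in the KO donors cannot be told apart from an effect of LRIG1 loss on expression of the transgenes, which was not tested. The chains differed from each other by -0.13 in log2 fold change (combined SE 0.141), but their folds had been seen before they were compared.

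Macrophage markers lay lower in OT1 KO by camera with a preset correlation, though not with an estimated correlation (adjusted p = 0.163 with an estimated correlation), and both genotypes came from the same mice. Melanoma markers did not fall with macrophage markers as a list. Their median lay 1.80 above that of macrophage markers (bootstrap SE 0.371). That SE came from resampling genes, so it does not measure the spread between libraries. B and natural killer cell markers had medians of 0.0037 and -0.16, though the natural killer list shares Gzma with the cytotoxic effector list. Less non-T material of every kind alike is therefore not shown. Melanoma markers were too low to exclude it, at 8.54 to 16.2 CPM summed per library. Less of several kinds of non-T material stays open and is not shown. Stroma and dendritic markers had medians of -1.13 and -1.02, with 0 of 7 and 4 of 8 members called. Camera with an estimated correlation gave adjusted p = 0.471 and 0.352. The summed stroma list overlapped, at 40.3 to 44.9 CPM in KO and 42.2 to 51.1 CPM in WT. The summed dendritic list lay at 81.6 to 92.9 CPM in KO and 122 to 175 CPM in WT. Its 4 called members were H2-Eb1, H2-Aa, H2-Ab1 and Cd74, all of class II antigen presentation, and 2 of the 8 lay above 0. Less macrophage material in the KO sorts cannot be told apart from other explanations: 88.9% of tested members (16 of 18, without Ctsb at 439 CPM in WT and Cd68) lay below 0, but the list was weighed because it was lower, and a sort for CD8 T cells would remove macrophages. A difference in how KO cells bind or take up macrophage material stays open and untested.

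The third pattern is the set of calls outside the marker and receptor lists. A common effect of LRIG1 loss as the only cause is argued against for 5 identifiers called in both sets, whose opposite signs lay beyond their SE. For Ifi208 the log2 fold change was -1.87 (SE 0.161) in Poly and 2.55 (SE 0.112) in OT1. They were picked for their opposite signs, so the interaction test adds nothing, and they include both copies of Erdr1, which share reads. For the 6 with the same sign a common effect cannot be told apart from background differences common to both KO groups. Variants flanking Lrig1 cannot be told apart either, with 0 calls within 10 Mb where 0.0977 and 0.516 were expected in the Poly and OT1 sets. Background segments that differ between KO and WT mice may account for part of the OT1 calls. Ctse, Chit1, Ube2t, Ptprv and Lad1 lie within 5 Mb on chromosome 1. Random draws of 55 genes, with near-identical families counted once, matched this with p = 0.0049 (permutation test, 10000 draws). Ctse and Ptprv rose, while Chit1 (log2 fold change -3.01), Ube2t and Lad1 fell. The draws left out only receptor segments and members of the fixed lists of other cells. Unlisted genes that fell along with the macrophage markers may therefore be among the 5.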

How the results depend on the processing

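The GC fits were added after the data were seen. Poly gene calls numbered 13 and became 96 with DESeq2, 24 with no filter, 21 with the strict filter, 37 with the replicate block, 70 in 1 fit of all samples, 38 with the GC trend removed and the block, and 5 to 21 without single libraries. OT1 calls numbered 74 and became 118, 134, 45, 145, 49 and 318 under the same settings, and 45 to 96 without single libraries. Removing the GC trend alone gave 15 and 109 calls, including 13 and 73 of the original calls. Interaction calls numbered 37 and became 94 with the replicate block, 114 with DESeq2, 127 from separate fits, and 25 to 59 without single libraries. The 6 called lists per set became 0 and 0 with an estimated correlation and 0 and 2 with fry, and 5 to 8 (Poly) and 6 to 8 (OT1) without single libraries. The correlation between sets ran from -0.046 to 0.033 without single libraries. Lrig1 in Poly had a log2 fold change of -1.20, also -1.20 with DESeq2, where it passed, and ran from -1.37 to -0.92 without single libraries, and in OT1 from -0.58 to -0.30. Reversed values were all of genes that did not pass: Havcr2 in Poly (-0.046 with the block, -0.028 with the block and GC trend removed, -0.13 to 0.26 without single libraries), Vsir in Poly (-0.28 to 0.079), Ifng in Poly (-0.32 to 0.20) and Gzmb in OT1 (0.020 with the GC trend removed, 0.019 also with the block, -0.064 to 0.015 without single libraries). The cause was not tested. Leaving out a Poly KO library leaves 1, which is assumed to vary like the other groups. In the OT1 set the block, added to the main fit, ended both list calls of fry (adjusted p = 0.109 for macrophage and 0.190 for V segments). There it changed no other call of a named gene or list. Added to the fit with the GC trend removed, it brought in Ifng (edgeR adjusted p from 0.0570 to 0.00123) and the immediate early list (camera adjusted p from 0.0609 to 0.0174). In the Poly set libraries numbered 1 and 3 gave correlations of deviations of -0.041 and 0.0044, so they were not read as pairs. There the block called the macrophage and dendritic lists, but not with an estimated correlation (adjusted p = 0.986 for both) or with fry (0.598 and 0.987), and did not call trafficking, tissue residency and V segments. Depth limited low genes: a count of 0 allows up to 0.122 CPM in Poly and 0.142 in OT1.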

Other observations

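The count over other splits of the libraries was planned, and the GC content tests were chosen after the result was seen. Other fixed lists were not called by camera in either set. Medians in Poly and OT1 were -0.07 and 0.02 for quiescence, -0.11 and -0.01 for heat shock, 0.04 and 0.08 for glycolysis, -0.03 and 0.0050 for oxidative phosphorylation, -0.04 and -0.05 for cholesterol synthesis, and 0.03 and -0.04 for apoptosis regulators. They were -0.03 and 0.03 for costimulatory receptors, -0.02 and 0.10 for cytokine receptors and STAT targets, -0.13 and 0.14 for partners of LRIG1 and VISTA, -0.67 and 0.0037 for B cell markers and -0.31 and 0.02 for CD4 and regulatory T cell markers. Lists called in 1 set had medians in the other of -0.05 for immediate early, -0.08 for interferon, 0.37 for dendritic and 0.14 for stroma genes in Poly, and of 0.06 for trafficking, 0.0055 for tissue residency and -0.16 for natural killer genes in OT1. T cell identity genes had medians of -0.09 and 0.04. The Poly median of the CD4 and regulatory T cell list does not show Cd4 itself. Cd4 held 90 and 57 counts in Poly KO libraries and 11, 8 and 1 in Poly WT libraries, and the cause was not tested. Adjusted over the list alone, 1 of the 7 tested members of that list passed higher in Poly KO and 0 lower. Of the 13 tested dendritic members, 2 passed higher and 0 lower. Over all genes, 0 members of either list passed in Poly. Neutrophil, erythroid and sex-linked lists had at most 2 tested members in either set.

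Receptor segments described the clonal makeup of the sets. In the OT1 libraries Trbv12 segments summed to 347 CPM ± 29.0 in KO and 713 CPM ± 57.6 in WT (SD, n = 3 each), and all other TRBV segments to 2.13 CPM ± 0.910 and 2.47 CPM ± 1.09. In the Poly libraries the other segments made up 81.9% to 90.1% of TRBV reads. Xist, on the list of sex-linked genes, measured 88.3 CPM ± 19.1 in Poly KO (n = 2) and 56.4 CPM ± 12.5 in Poly WT (n = 3). In the OT1 set it measured 1273 CPM ± 145 in KO and 1261 CPM ± 9.39 in WT (n = 3 each). All Poly libraries are titled female, and the cause of their lower Xist level was not tested.

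The OT1 comparison of genotypes called 74 genes, and 2 of the 10 splits of the 6 libraries into groups of 3 gave as many, the real one included. So few splits cannot give a share under 0.05. The highest other split put WT replicate 1 with KO replicates 1 and 2 and called 1174 genes, which points to a structure of the samples. That split parted 1 pair of equal replicate numbers, and the 3 other splits that part all 3 pairs called 0 genes with edgeR. The 1174 genes had a median absolute log2 fold change of 0.33, against 1.91 for the 74, and shared 0 genes with them. Their 846 higher genes had a median transcript GC content of 57.0% and their 328 lower genes 41.2%, against 49.1% for genes not called. The 17 higher and 57 lower genes of the genotype comparison had medians of 49.9% and 50.6%. With the GC trend removed, that split called 19 genes and the genotype comparison called 109, including 73 of the 74. With the replicate block as well, the genotype comparison called 318 genes, again including 73 of the 74.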
